A study of Mus musculus with 8 samples.

How the data were processed

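RNA-seq was done on microglia sorted from brains of male 5xFAD mice, with 4 saline and 4 ethanol libraries. Per the labels' protocols, cDNA was amplified from 500 pg of total RNA per library (SMARTer Ultra Low Input chemistry, version 4), 150 pg of it went into a NexteraXT preparation, and the libraries were sequenced on a NovaSeq X in paired ends of 150 nt. Per the submitters' processing notes, bcl2fastq 2.19.1, STAR 2.7.9a, Subread with featureCounts 2.0.1, Salmon 1.5.2, DESeq2 and R 4.2.2 were used with the mouse build GRCm39. The role and order of these tools, their parameters and the gene annotation are not given in the sources used here. NexteraXT libraries do not mark strand, so reads of a gene and an overlapping antisense gene cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, have uncertain values.

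The authors deposited 1 table of signal values per gene, which its name calls DESeq2-normalized counts, that is, counts divided by a size factor per library. It holds 56832 rows, named by gene symbol or, for 1544 rows, by Ensembl identifier, and 26812 rows had a value above 0. Dividing each library's values by its smallest non-zero value gave whole numbers within 1e-06 for 100% of the non-zero values, so whole reads were recovered. DESeq2 size factors recomputed from these reads matched the steps of the deposited values within 3.55e-15. Library columns were matched to samples by the library names in the labels. Totals were 14271351 to 17231301 assigned reads per library. Intervals from limma cover the spread between libraries. The libraries carry no molecular identifiers, so reads amplified from a small RNA input are not independent molecules.

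Deposited values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend for the variance, on the 14428 genes with a mean of at least 10 over the 8 libraries. The fit held an intercept and the group, and the test was two-sided with a Benjamini-Hochberg threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. Gene lists were tested with camera at its preset correlation of 0.01, over 32 lists with at least 3 tested members out of 34 fixed lists. The lists of erythrocyte markers and of choroid plexus and ependyma markers had no tested member. Composition measures and principal components were compared by a two-sided exact permutation test over 70 arrangements, which cannot give a p below 0.0286.

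Samples were grouped by their titles. The design, tests, gene lists and most alternatives were fixed before the data were examined. Named genes followed a fixed rule. With no gene past the adjusted threshold, the 10 genes with the smallest unadjusted p in each direction were named, among genes with a symbol that is not a numbered gene model and a mean of at least 50. A further 18 genes were named whatever their result, namely Apoe, Trem2, Tyrobp, Cst7, Lpl, Itgax, Clec7a, Spp1, Axl, Cd68, P2ry12, Tmem119, Cx3cr1, Csf1r, Il1b, Tnf, Tlr4 and Ifit3. Genes in the description of library composition and of samples 1 to 4 fall outside this rule and were chosen after their values were seen, except the markers fixed for the check of sex.

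Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, quantile normalization, a robust variance model, array quality weights, the sample number as a block, the number in the library name as a covariate, an adjusted threshold of 0.10, leaving out each library, and edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and voom on the recovered reads. Lists were also tested with an estimated correlation and with fry. Fits with samples 1 and 2 against samples 3 and 4 as a term, and within each of these sets, were added after seeing the data. The tests were tried on simulated data in which 200 of 14428 genes were changed, with 50 genes at each fold. The 36 tested genes of the interferon list were also raised by 0.3 on the log2 scale and were not counted as unchanged. Genes were drawn independently of each other. Over 5 simulations of the comparison of ethanol with saline, limma recovered 6.4% of genes changed 1.25-fold, 38.8% at 1.5-fold, 61.2% at 2-fold and 78.4% at 4-fold, and called 33 of 70964 unchanged genes. Transcript lengths came from a GENCODE annotation of GRCm38, an older build than the table's, matched by symbol, and no coordinates are given.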

Results

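Microglia, the resident macrophages of the brain, were collected by fluorescence-activated sorting from young adult male 5xFAD mice, a transgenic line that makes mutant human amyloid precursor and presenilin proteins and forms amyloid plaques. The mice had been injected intraperitoneally on 5 days of each week over 4 weeks, then left without injections for 2 weeks. The ethanol group received 3 g/kg as a 20% solution and the control group received saline, and the comparison asks whether this exposure altered the microglial transcriptome. Each group had 4 RNA-seq libraries, numbered 1 to 4 after their titles. Between 14271351 and 17231301 reads per library were assigned to genes, and 14428 genes had a mean of at least 10 normalized counts. The titles name the libraries as separate samples but do not say that each came from its own mouse, so every p-value measures the spread between these libraries, part of which can be technical.

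The libraries had the profile of brain microglia in both groups. Cst3, which encodes the protease inhibitor cystatin C, had the highest mean over the 8 libraries, at 299801 normalized counts. Other abundant transcripts included those of the purinergic receptor gene P2ry12 at 171085, the cathepsin D gene Ctsd at 132844 and the growth factor receptor gene Csf1r at 128225. Tmem119, a microglial surface marker, reached 81838 ± 4394 in saline and 85473 ± 1709 in ethanol libraries (SD, n = 4 each). Xist, the RNA that silences an X chromosome in females, had at most 3.01 normalized counts in any library and the Y-linked Ddx3y had at least 2056 in each of these male samples.

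Transcripts of other cells were scarce. Border macrophage markers made up 0.124 ± 0.0145% of the normalized counts in saline and 0.116 ± 0.0101% in ethanol libraries (SD, n = 4 each). The neutrophil share was 0.0993 ± 0.036% and 0.0905 ± 0.0227%, the astrocyte share 0.0603 ± 0.00707% and 0.0614 ± 0.00914%, and the lymphocyte share 0.0575 ± 0.00414% and 0.0555 ± 0.00391%. Of the 22 lymphocyte markers, 4 had a mean of at least 10, so that share rests mostly on few genes. Which cells made the transcripts in these shares was not tested, and microglia could have made some of them. Oligodendrocyte lineage markers made up 0.0204% in either group. Markers of monocytes, neurons, and endothelial and mural cells stayed below 0.01% in each library, and those of erythrocytes and of choroid plexus below 0.001%. Transcripts of the 13 protein-coding mitochondrial genes made up 1.11 ± 0.186% in saline and 1.06 ± 0.183% in ethanol, without mitochondrial ribosomal RNA. Ribosomal protein transcripts made up 1.24 ± 0.164% and 1.22 ± 0.185%. The 50 most abundant genes held 20.0 ± 1.11% and 20.3 ± 0.862%. None of the 14 composition measures differed between the groups in a two-sided exact permutation test, where the smallest unadjusted p was 0.143, for endothelial and mural markers, and the smallest p the design allows is 0.0286.

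No single gene was called higher or lower in ethanol than in saline microglia. In limma, 0 of 14428 genes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 245 genes higher and 279 lower, 3.63% of those tested, against 721 genes, or 5%, that chance gives. The count models also called 0 genes, and at an unadjusted p under 0.05 they gave 495 genes in edgeR, 546 in voom and 777 in DESeq2, which ran without the filter, on 26782 genes. The values of the 4 ethanol and 4 saline libraries did not overlap for 335 genes, which is 2.32%, where chance gives 2.86%. Within samples 1 and 2 alone, and within samples 3 and 4 alone, limma called 0 genes as well.

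**Figure D1:**
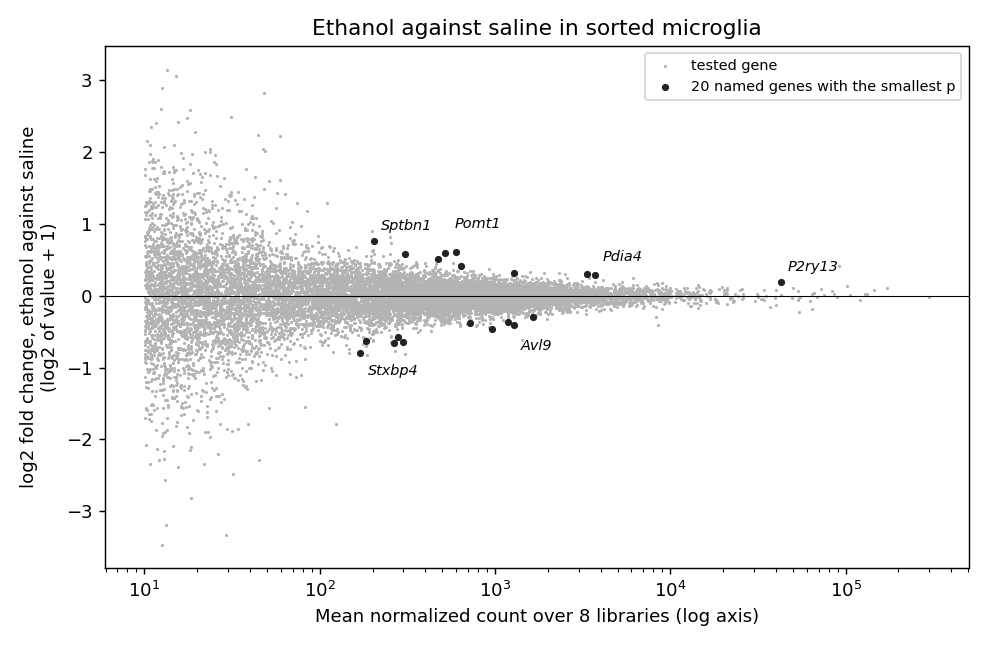
Each point is 1 of the 14428 tested genes, placed by its mean normalized count over the 8 libraries (log axis) and its log2 fold change of ethanol against saline, on log2 of the value plus 1; dark points are the 20 named genes with the smallest unadjusted p, 10 in each direction. The scatter narrows as the mean rises, and no gene passed the adjusted threshold of 0.05.

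Abundant genes set the tighter limits on an ethanol effect. Of the 3450 genes with a mean of at least 1000 normalized counts, 99.5% had a 95% interval that excluded a change of 1.5-fold or more in either direction, and 99.9% excluded a 2-fold change. For the 6338 genes between 100 and 1000 these shares were 73.6% and 97.4%, and for the 4640 genes between 10 and 100 they were 0.431% and 20.2%. In data simulated from these libraries, limma called 38.8% of genes changed 1.5-fold, 61.2% of genes changed 2-fold and 78.4% of genes changed 4-fold. Each simulation changed 200 of 14428 genes at once and drew genes independently of each other, so these rates hold for that setting. Recovery with fewer changed genes, or with genes that vary together, was not tested. Most tested genes with fewer than 100 normalized counts had intervals that leave room for a 2-fold change.

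The 10 genes with the smallest unadjusted p on the higher side, none of which passed the adjustment, were Pomt1, Sptbn1, Pdia4, Fzd7, Lcmt2, Acot9, Etv5, P2ry13, Manea and Tmem167b. Pomt1, an enzyme of protein O-mannosylation, had 413 ± 21.1 normalized counts in saline and 629 ± 108 in ethanol (SD, n = 4 each), a fold of 1.51 with a 95% interval of 1.23 to 1.84. Sptbn1, which encodes a spectrin of the membrane skeleton, had 151 ± 26.6 and 255 ± 28.8, a fold of 1.70 (1.29 to 2.24). Pdia4, a protein disulfide isomerase of the endoplasmic reticulum, had 3366 ± 47.3 and 4103 ± 288, a fold of 1.22 (1.09 to 1.35). P2ry13, a purinergic receptor of resting microglia, had 39908 ± 1571 and 45472 ± 2275, a fold of 1.14 (1.05 to 1.23). In these 4 genes each ethanol library lay above each saline library, but the limma adjusted p was 0.997 for each of them.

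On the lower side the 10 genes were Avl9, Usp31, Etaa1, Filip1l, Crebrf, Cnot6l, Stxbp4, Zfp568, Col6a3 and Calhm2. Avl9 had 1452 ± 108 normalized counts in saline and 1104 ± 157 in ethanol (SD, n = 4 each), a fold of 0.756 (95% interval 0.646 to 0.885). Etaa1, which encodes an activator of the ATR kinase in replication stress, had 336 ± 48.3 and 224 ± 19.1, a fold of 0.671 (0.532 to 0.848). Crebrf, a regulator of CREB3-type transcription factors, had 1816 ± 112 and 1478 ± 77.0, a fold of 0.814 (0.718 to 0.923). Col6a3, a collagen VI chain, had 322 ± 47.1 and 207 ± 52.9, a fold of 0.633 (0.476 to 0.843). The limma adjusted p was 0.997 for each of the 10.

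Homeostatic microglial genes had values close to equal in the groups. Of the 22 genes of this list 0 passed the test, adjusted over all genes or adjusted over the list alone, and their median log2 fold change was 0.04 (camera adjusted p = 0.373). P2ry12 had 165119 ± 5071 normalized counts in saline and 177052 ± 4761 in ethanol (SD, n = 4 each), a fold of 1.07 (95% interval 1.00 to 1.15). Its direction turned under quantile normalization, where the log2 fold change was -0.06. Cx3cr1, the fractalkine receptor gene, had 96998 ± 5463 and 107098 ± 17522, a fold of 1.10 (0.970 to 1.24), and ethanol 3 stood apart at 133274. Tmem119 had a fold of 1.05 (0.972 to 1.12). Csf1r had a fold of 1.01 (0.937 to 1.09), and its log2 fold change was -0.05 under quantile normalization.

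Genes of disease-associated microglia, the state that gathers at amyloid plaques, did not differ past the threshold either. Of 34 tested members 0 passed, adjusted over all genes or adjusted over the list alone, 10 had positive and 24 negative fold changes, and the median log2 fold change was -0.07 (camera p = 0.0403, adjusted p = 0.258; p = 0.491 with an estimated correlation). Apoe, the lipid carrier gene, had 9185 ± 2655 normalized counts in saline and 7436 ± 1806 in ethanol (SD, n = 4 each), a fold of 0.815 (95% interval 0.639 to 1.04). Trem2, the lipid-sensing receptor gene of plaque-associated microglia, had 23637 ± 1024 and 22548 ± 1244, a fold of 0.953 (0.876 to 1.04), and its adaptor gene Tyrobp had a fold of 0.951 (0.832 to 1.09). The folds were 0.846 for Cst7 (0.624 to 1.15), 0.823 for Lpl (0.639 to 1.06), 0.879 for Itgax (0.597 to 1.29), 0.956 for Clec7a (0.641 to 1.43), 0.962 for Axl (0.697 to 1.33) and 1.01 for Cd68 (0.913 to 1.13). Spp1, or osteopontin, was near the detection limit at 33.3 ± 17.0 and 15.6 ± 8.38, a fold of 0.504 (0.226 to 1.13). Within samples 1 and 2 and within samples 3 and 4, a division made after seeing the data, the log2 fold change of Spp1 was -0.13 and -1.84. The list passed in the lower direction without saline 1, at a camera adjusted p of 0.00359, and without ethanol 4, at 0.0257, and with an estimated correlation the adjusted p-values were 0.994 and 0.974. Leaving out saline 1 or ethanol 4 tilts the saline group toward samples 3 and 4 relative to the ethanol group. The median log2 difference of the list between samples 1 and 2 and samples 3 and 4 was -0.23, in the same direction. With that division as a term the camera p was 0.0481 (adjusted p = 0.192).

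**Figure D2:**
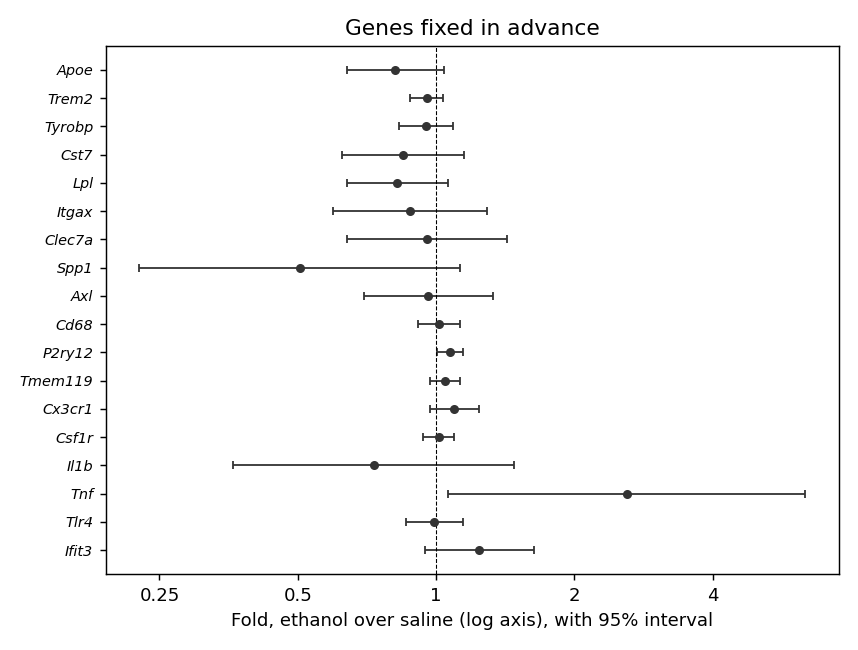
Fold of ethanol over saline (log axis) for the 18 genes fixed before the data were examined, as points, with horizontal bars for the 95% limma interval from 4 libraries per group. The intervals of 16 genes span 1, those of P2ry12 (1.004 to 1.15, with the direction turned under quantile normalization) and Tnf (1.06 to 6.35) lie above it, and the smallest p adjusted over these 18 genes was 0.340.

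The cytokine genes Tnf and Il1b were expressed at low levels, and neither they nor Tlr4 passed the test. Tnf, a proinflammatory cytokine gene, had 11.1 ± 6.48 normalized counts in saline and 30.2 ± 16.7 in ethanol (SD, n = 4 each), a fold of 2.60 (95% interval 1.06 to 6.35) on the log2 of the value plus 1. The log2 fold change of Tnf was 0.78 within samples 1 and 2 and 1.97 within samples 3 and 4. Il1b had 27.3 ± 5.58 and 21.3 ± 10.6, a fold of 0.731 (0.361 to 1.48). Tlr4, the endotoxin receptor gene, had 2897 ± 358 and 2867 ± 285, a fold of 0.992 (0.861 to 1.14). Limma p-values adjusted over the 18 fixed genes were 0.340 for Tnf, 0.590 for Il1b and 0.902 for Tlr4. None of the 24 tested members of the list of inflammatory cytokines and NF-kB targets passed, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.972), and its median was -0.02 while its mean was 0.11 on the log2 scale. The Toll-like receptor and inflammasome list (28 genes, camera adjusted p = 0.972), complement (14 genes, adjusted p = 0.995), antigen presentation (24 genes, adjusted p = 0.972) and phagocytic receptors with amyloid uptake (34 genes, adjusted p = 0.583) likewise had 0 members past either adjustment.

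The list of type I interferon response genes did not pass, and the sign of its difference varied with the libraries compared. Over all 8 libraries 28 of 36 tested members had a positive fold change, with a median of 0.15 on the log2 scale, 0 members passed, adjusted over all genes or adjusted over the list alone, and the list had a camera p of 0.00996 (adjusted p = 0.159; p = 0.441 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, had 297 ± 37.3 normalized counts in saline and 377 ± 93.9 in ethanol (SD, n = 4 each), a fold of 1.24 (95% interval 0.944 to 1.63). The list score, the mean log2 deviation of its genes, was 0.56 in ethanol 3 and 0.29 in ethanol 4, against 0.21 in saline 3 and -0.23 in saline 4. In samples 1 and 2 the ethanol scores of -0.32 and -0.24 lay below the saline scores of -0.11 and -0.15. The camera adjusted p was 0.0389 without saline 3, 0.000402 without ethanol 1 and 0.00838 without ethanol 2, and without ethanol 3 the direction turned, with an adjusted p of 0.999. With an estimated correlation the adjusted p-values were 0.990, 0.956 and 0.951 for the first 3 of these. Leaving out saline 3, ethanol 1 or ethanol 2 tilts the ethanol group toward samples 3 and 4 relative to the saline group. The median log2 difference of the list between samples 1 and 2 and samples 3 and 4 was -0.38, in the same direction. With that division as a term, added after seeing the data, the list over all 8 libraries had a smaller camera p of 0.00246. Its adjusted p of 0.0664 did not pass, and this fit used the preset correlation. Monocyte markers, which share no gene with this list, had scores of 1.30 in ethanol 3, 1.26 in ethanol 4, 1.29 in saline 3 and -0.39 in saline 4, so that saline 4 was the lowest of these 4 libraries in both lists. Scores of neutrophil and border macrophage markers, which share no gene with it either, differed between ethanol and saline by -0.65 and -0.70 in samples 1 and 2 and by 0.62 and 0.48 in samples 3 and 4. Astrocyte markers (-0.26 and 0.14) and endothelial and mural markers (-0.57 and 0.14, 5 tested genes) had the same signs. Oligodendrocyte lineage markers had the opposite signs (0.20 and -0.28, 6 tested genes), and neuron, lymphocyte and monocyte markers were positive in both sets. These signs were not particular to markers of other cells, and antigen presentation genes (-0.27 and 0.12) also had those of the interferon list. Proliferation genes (0.23 and -0.18) had the opposite signs.

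Among metabolic, stress and signalling lists, 3 had a camera p under 0.05 before adjustment and none after it. TGF-beta signalling, which maintains microglial identity, had 14 of 16 tested members with a positive fold change and a median of 0.08 (camera p = 0.0052, adjusted p = 0.159; p = 0.103 with an estimated correlation). Its adjusted p was 0.0264 without saline 2 and 0.0143 without ethanol 3, with adjusted p-values of 0.941 and 0.999 under an estimated correlation. Cholesterol biosynthesis had 16 of 23 members positive and a median of 0.10 (camera p = 0.0276, adjusted p = 0.250; p = 0.124 with an estimated correlation), and its adjusted p was 0.0466 without ethanol 1 (adjusted p = 0.696 with an estimated correlation). The unfolded protein and integrated stress response had 19 of 23 members positive and a median of 0.05 (camera p = 0.0313, adjusted p = 0.250; p = 0.204 with an estimated correlation). In that list 1 gene, Pdia4, passed when adjusted over the list alone, and 0 passed over all genes tested. No other list had a member past either adjustment.

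Cytosolic ribosomal protein genes had a median log2 fold change of -0.04 over 81 genes (camera p = 0.0805, adjusted p = 0.368; p = 0.775 with an estimated correlation). The list passed in the lower direction when saline 1, saline 2, ethanol 3 or ethanol 4 was left out, at adjusted p-values of 0.0105, 0.0264, 0.00266 and 0.000894. With an estimated correlation these adjusted p-values were 0.994, 0.941, 0.999 and 0.974. Each of these omissions tilts the saline group toward samples 3 and 4 relative to the ethanol group. The list was lower in samples 1 and 2 than in samples 3 and 4 (median log2 difference -0.34). These passes alone therefore cannot be credited to ethanol. A fit with that division as a term, added after seeing the data, gave a camera p of 0.0144 (adjusted p = 0.116). Within samples 1 and 2, where this tilt is absent, the list was lower in ethanol (camera adjusted p = 0.000409). With an estimated correlation that adjusted p was 0.989. The list score differed by -0.11 there and by -0.01 within samples 3 and 4. The mitochondrially encoded list had a median of -0.13 over 8 genes (camera p = 0.0608, adjusted p = 0.324), and its adjusted p was 0.0264 without saline 2 (adjusted p = 0.941 with an estimated correlation). This list was also lower in samples 1 and 2 than in samples 3 and 4 (median log2 difference -0.35), and the same limit holds. With that division as a term its camera p was 0.0071 (adjusted p = 0.0757) at the preset correlation. Without the term, camera with an estimated correlation gave p = 0.496. Nuclear oxidative phosphorylation genes had a median of -0.02 (69 genes, camera adjusted p = 0.972).

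The remaining lists did not pass. Camera adjusted p-values were 0.995 for the lysosome, ethanol and aldehyde metabolism, glycolysis and hypoxia, and the circadian clock. They were 0.972 for lipid efflux and fatty acid handling, the oxidative stress response, and Alzheimer risk and amyloid processing, 0.868 for proliferation and the glucocorticoid response, and 0.567 for immediate early and dissociation stress genes. For markers of other cells they were 0.583 for neurons and monocytes, 0.868 for border macrophages, 0.972 for neutrophils and lymphocytes, and 0.995 for astrocytes, the oligodendrocyte lineage, and endothelial and mural cells. Across all 32 lists 0 passed with camera, 0 with an estimated correlation and 0 with fry.

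**Figure D3:**
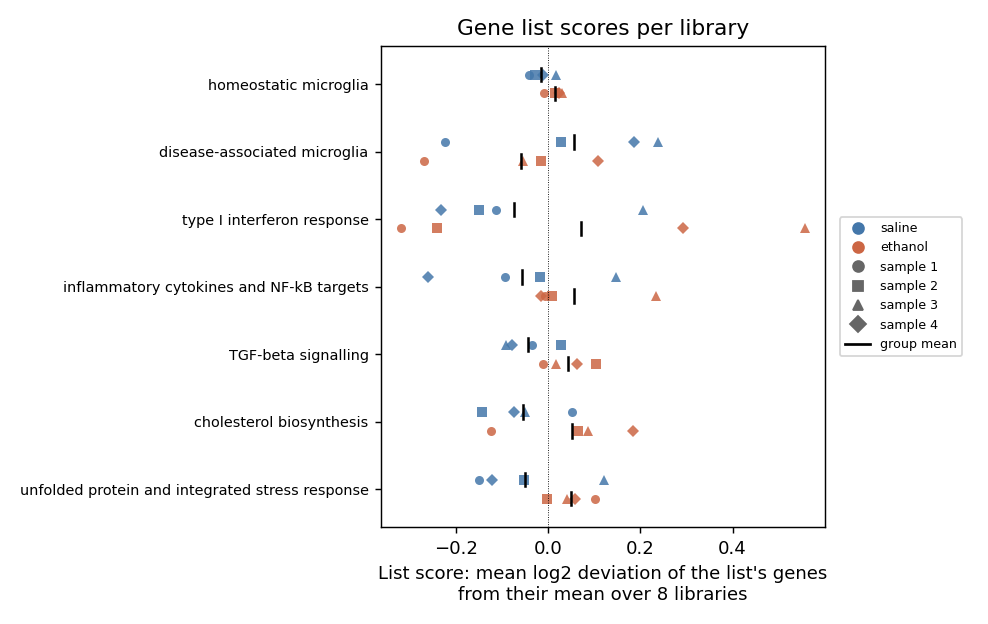
List scores, the mean log2 deviation of a list's genes from their mean over 8 libraries, for 7 of the lists; each symbol is 1 library, its colour the group and its shape the sample number, and black bars are group means of 4 libraries. The groups overlap in each list shown, and the interferon scores spread from -0.32 in ethanol 1 to 0.56 in ethanol 3.

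The treatment was not a main axis of variation between the libraries. Component 1 held 20.1% of the variance of the log2 values and component 2 held 16.9%, and the groups did not differ on components 1 to 3 in an exact permutation test, where the smallest of the 3 p-values was 0.600. Pearson correlations of the log2 values across genes had a median of 0.957 within groups and 0.958 between groups. Pairs within a group differed by 9.27 to 21.1 chi-square units per gene, against counting error only, so no library was treated as a resequenced copy of another. Repeat preparations from 1 mouse could also exceed counting error and are not excluded. On component 1, samples 1 and 2 of both groups lay between -31.4 and -13.9, and samples 3 and 4 between 4.58 and 60.7. Protein-coding mitochondrial transcripts made up 0.938 ± 0.0767% of normalized counts in samples 1 and 2 and 1.23 ± 0.0766% in samples 3 and 4 (SD, n = 4 each). Each of these sets of samples holds 2 saline and 2 ethanol libraries, so this difference does not follow the treatment.

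**Figure D4:**
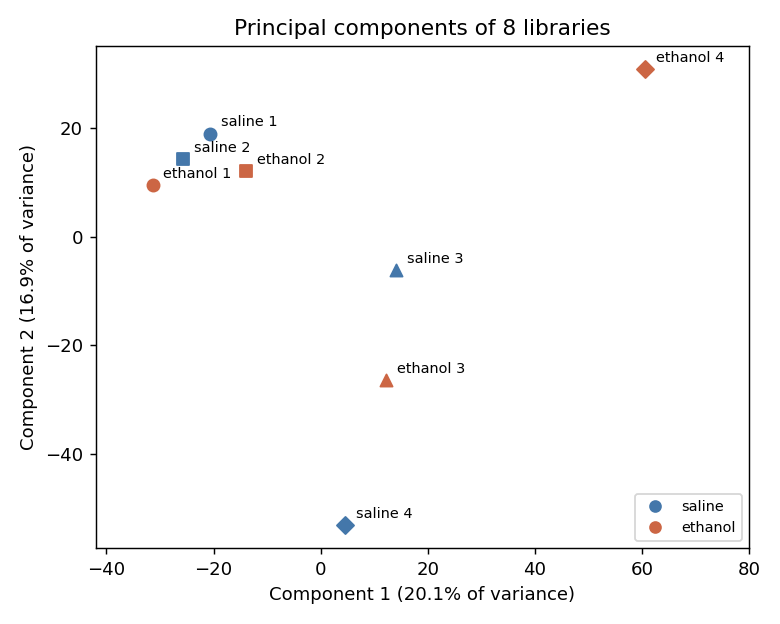
Libraries on the first principal components of log2 normalized counts, with saline in blue and ethanol in orange, labelled by group and sample number; axis labels give each component's share of the variance, 20.1% and 16.9%. The groups are intermixed, and samples 1 and 2 lie to the left of samples 3 and 4.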

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

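In 10 of the 170 groups of 4 libraries examined, 1 library lay far from the other 3, with a gap to the nearest of them, as a share of the whole range, above Dixon's 95% critical value for 4 samples. Chance gives about 1 in 20 such groups, or 8.5 here. The tests of explanations in the 2 paragraphs that follow these values were chosen after the result was seen, except the test of transcript length. The bound of that test was set beforehand, but its measure of length was changed after a first one had been tried.

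Sptbn1 had 298 normalized counts in ethanol 4 against 240 to 243 in the other ethanol libraries. Fzd7 had 576 in saline 1 against 427 to 446 in the other saline libraries. Spp1 had 28.1 in ethanol 2 against at most 12.3, and Cx3cr1 had 133274 in ethanol 3 against 96246 to 100006. Total reads in ethanol 1 were 14271351 against 15438223 to 15589394. Erythrocyte markers made up 0.000128% of normalized counts in saline 4 and 0.000617% in ethanol 3, both near the detection limit. Ethanol 3 also stood apart in 2 list scores, with 0.23 for inflammatory cytokines and NF-kB targets and -0.19 for the circadian clock. The oligodendrocyte lineage score was -0.48 in saline 2, where the other saline libraries lay between 0.13 and 0.24.

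Limma called 0 genes between ethanol and saline, a number that 35 of the 35 splits of the 8 libraries into 4 and 4 reach by construction, so this count says nothing about chance; the highest of the other splits called 123. The number of genes at an unadjusted p under 0.05 was 524 for the real split, and 29 of the 35 splits gave at least as many. Differences between samples 1 and 2 and samples 3 and 4 could hide genes that respond to ethanol, but a fit with that term also called 0 genes, with 682 at an unadjusted p under 0.05. Effects too small for this design stay open, as does the absence of an ethanol effect after the 2 weeks of withdrawal.

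The split that called 123 genes set samples 1 and 2 of both groups against samples 3 and 4. Each set holds 2 saline and 2 ethanol libraries, so the treatment does not explain these calls. It was picked after its values were seen, so its rank, 1 of 35 with 9 genes in the next highest, leaves chance open. Total reads overlapped between these sets (14271351 to 16654661 and 15438223 to 17231301; exact permutation p = 0.657), which argues against different total reads as the cause. Blood leukocytes could add mitochondrial and ribosomal transcripts to samples 3 and 4. The rise of neutrophil and monocyte marker counts was 0.969% of the summed rise of those transcripts, between -0.585% and 3.92% as each library was left out. The summed marker counts were 15312.5 in samples 1 and 2 and 16231.8 in samples 3 and 4. Markers called between the sets, such as Retnlg (60.5 and 375) and Mmp8 (30.1 and 210), were a small part of these sums. Other markers set most of the sum, so it cannot decide whether leukocytes contributed. Poorer recovery of short transcripts in samples 1 and 2 was set beforehand to give a correlation with transcript length of at least 0.10, and this was met narrowly. Across 13438 genes, which are not independent replicates, the log2 difference had a Spearman correlation of 0.105 with transcript length. Ribosomal, oxidative phosphorylation and mitochondrial genes were left out. The correlation ran from 0.085 to 0.116 as each library was left out, a check that the bound did not include. Lengths of protein-coding transcripts alone, tried first, gave 0.195, which also reached the bound, but covered only 78.5% of the tested genes. Since the measure of length was changed and the correlation is small, this cause stays open.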

How the results depend on the processing

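The fit with samples 1 and 2 against samples 3 and 4 as a term, and the fits within each of these sets, were added after seeing the data. Counts of genes higher and lower in ethanol were 0 under each of the 16 other settings and as each of the 8 libraries was left out. The saline and ethanol libraries of samples 2, 3 and 4 share the number in their library names (165, 163 and 164), and those of sample 1 do not. Deviations of same-numbered libraries correlated at 0.014 to 0.080. Differently numbered libraries were not compared in this way, so a pairing by sample number is not excluded. The fit with the replicate block called 0 genes and 0 lists. The number of lists shifted moved from 0 to between 0 and 3 as each library was left out. It moved to 2 within samples 1 and 2 (border macrophage markers and ribosomal proteins, lower) and 2 within samples 3 and 4 (interferon response and monocyte markers, higher), each fitted on 4 libraries. With an estimated correlation none of these passed. Leaving out 1 library makes the groups differ in their shares of samples 1 and 2 and of samples 3 and 4. A list that differs between these sets can then pass without an ethanol effect. For the interferon list the adjusted p ran from 0.000402 to 0.999 over left-out libraries, with the direction turned without ethanol 3 and within samples 1 and 2 (0.273), and was 5.5e-07 within samples 3 and 4. The camera direction of the unfolded protein list, which is relative to the other genes, turned within samples 3 and 4 (adjusted p = 0.928). Its own score there was still higher in ethanol, by 0.05. Of the 38 named genes, 28 kept their direction under each setting, including the 20 with the smallest p, and 0 passed under any. Those 20 were picked for their p in these same libraries, so their kept direction is no support for it. Log2 fold changes turned under quantile normalization for Cd68 (-0.00237), P2ry12 (-0.055) and Csf1r (-0.046), and under array weights for Tlr4 (0.00973). Within samples 1 and 2 they turned for Cst7 (0.31), Itgax (0.15) and Tlr4 (0.11), and within samples 3 and 4 for Apoe (0.10), Clec7a (0.088) and Csf1r (-0.039). Over left-out libraries they ran from -0.32 to 0.11 for Axl, -0.029 to 0.073 for Cd68, -0.33 to 0.18 for Clec7a, -0.018 to 0.063 for Csf1r, -0.40 to 0.019 for Itgax, -0.071 to 0.060 for Tlr4 and -0.13 to 0.021 for Tyrobp. The cause was not tested for these shifts. Composition kept 0 measures past the threshold without each library, but this adjusted test could hardly pass. Between samples 1 and 2 and samples 3 and 4 the mitochondrial share reached an exact permutation p of 0.0286, the smallest possible, with an adjusted p of only 0.10. The same p-values held for the ribosomal protein share (1.09% and 1.36%) and the share of the 50 most abundant genes (19.4% and 21.0%). They also held for border macrophage markers (0.129% and 0.111%). The smallest exact permutation p on components 1 to 3 was 0.743 at a mean of at least 50 and 0.657 with unit variance. Precision was lowest for genes between 10 and 100 normalized counts, of which 20.2% excluded a 2-fold change; how far depth sets this was not tested.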

Other observations

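The tests and genes in this part were chosen after the values were seen. Between samples 1 and 2 and samples 3 and 4, limma called 96 genes lower and 27 higher in samples 1 and 2, each set holding 2 saline and 2 ethanol libraries. Of the 96, 24 encode cytosolic ribosomal proteins, out of 81 tested (camera adjusted p = 0.263 for this list with an estimated correlation, so the list's call is lost with it). A further 7 are mitochondrial transcripts, 5 of them protein-coding, with the ribosomal RNA mt-Rnr2 and the transfer RNA mt-Tp. Rps19 had a log2 difference of -0.55 ± 0.08 (SE), and mt-Co1, a subunit of cytochrome oxidase, had -0.53 ± 0.07. Tyrobp was also among the lower genes (-0.28 ± 0.06). Ace, a gene of the monocyte marker list, had 0.773 ± 0.968 normalized counts in samples 1 and 2 and 58.7 ± 27.2 in samples 3 and 4 (SD, n = 4 each), whereas Cd163, a marker of border macrophages, was higher in samples 1 and 2 (2.13 ± 0.42, SE, on the log2 scale). Camera put 16 of 32 lists past the threshold for this split, and 0 with an estimated correlation. By library name, the 3 libraries numbered 165 all lie in samples 1 and 2 and both libraries numbered 163 in samples 3 and 4, and the labels do not say what these numbers mean.

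The interferon list was higher in ethanol in samples 3 and 4, by 0.44 on the log2 scale with 32 of 36 members higher, and lower in samples 1 and 2, at -0.15 with 23 of 36 members lower. The difference between these differences was 0.59 (two-sided exact permutation within the sets, p = 0.0556, the smallest that 36 arrangements can give), and in limma 0 genes were called for such a difference of differences and 595 had an unadjusted p under 0.05, where chance gives 721. A candidate explanation is that interferon genes vary together between libraries whatever the treatment; camera on the difference of differences, with the correlation among the list's genes estimated at 0.170, gave p = 0.0797 (adjusted p = 0.881), which neither excludes it nor shows it. Scores of other lists moved as well, given here as ethanol minus saline in samples 1 and 2 and in samples 3 and 4. Marker lists with the signs of the interferon list were neutrophils (-0.65 and 0.62), border macrophages (-0.70 and 0.48), endothelial and mural cells (-0.57 and 0.14, 5 tested genes) and astrocytes (-0.26 and 0.14). Other lists with these signs were antigen presentation (-0.27 and 0.12), phagocytic receptors (-0.18 and 0.05), complement (-0.17 and 0.07), Alzheimer risk (-0.11 and 0.10), oxidative stress (-0.09 and 0.04) and glycolysis (-0.02 and 0.07). The opposite signs occurred for the oligodendrocyte lineage (0.20 and -0.28, 6 tested genes), proliferation (0.23 and -0.18), immediate early genes (0.07 and -0.36) and the lysosome (0.03 and -0.01). Among marker lists, differences were positive in both sets for neurons (0.28 and 0.23), lymphocytes (0.36 and 0.08) and monocytes (0.29 and 0.83). The monocyte list had a camera adjusted p of 0.0205 in samples 3 and 4, and p = 0.317 with an estimated correlation. Border macrophage scores did not follow the interferon scores from library to library. They were -0.31 and -0.61 in ethanol 3 and 4, where interferon scores were highest, and 1.48 in saline 2, where the interferon score was -0.15. RNA from other cells and a response to ethanol in some of the samples stay open.

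Of the 13 protein-coding mitochondrial genes, 5 were almost without reads in each library. The mt-Co3 gene had 1 to 23 reads, mt-Atp6 0 to 12, mt-Nd4l 1 to 10, mt-Co2 0 to 8 and mt-Atp8 0 to 6, while mt-Cytb had 40480 to 66921 and mt-Co1 27329 to 52650. The share of mitochondrially encoded transcripts given for each library rests on the other 8 genes.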
